A study of Mus musculus with 6 samples.

How the data were processed

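RNA of POS-challenged and unchallenged primary mouse RPE cultures, 3 libraries per group, was extracted with Trizol and enriched for poly(A) RNA, and each library was run on 2 lanes of a Genome Analyzer IIx, per the labels' protocols. The submitters' processing notes name GSNAP, DESeq2 and the genome build mm10, with no versions and no parameters. Their versions, the gene annotation, the counting tool and whether strand was used are not given in the sources used here. One library was made per biological replicate, per the labels, and whether replicates were separate litters or days is not stated there.

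The deposited table holds 12556 genes with an Entrez Gene identifier and a symbol, except for 84 without a symbol. Its 6 library columns are a signal that the authors scaled, and per the values each is a gene's read count divided by a library size factor, as DESeq2 gives normalized counts. Their mean equals the base mean column. Whole reads were recovered for 100% of the values in each library (within 0.001 of a whole number), with size factors between 0.901 and 1.103. Reads summed over the table came to 24869273 to 30420028 per library. The deposited table also gives the authors' log2 fold change and its error, a score per gene (the Wald statistic) and the raw and adjusted p-values, per the file headers. Their log2 fold changes are smaller than those of limma (median ratio 0.818 over the 308 genes they call), as with a shrinkage prior. A raw p is missing for 13 genes and an adjusted p for 500. Every gene in the table has at least 87 reads over the 6 libraries, so genes below that level were not analysed here. Of the identifiers, 12346 were matched to the RefSeq gene table of assembly GRCm38.p6, the build that mm10 denotes, which gave the coordinates.

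Because the values are scaled counts, they were tested on a log scale rather than with a count model, as had been laid down for such a table before the data were examined. The test was limma (version 3.58.1 in R 4.3.3) with a trend on log2(value + 1), genes with a mean of at least 10 (which removed no gene), group as the only term and Benjamini-Hochberg adjustment, with calls at an adjusted p of 0.05. Residual degrees of freedom were 4 and limma's prior added 3.22. An exact permutation test of a single gene with 3 against 3 cannot go below a two-sided p of 0.1 and was not used.

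Fixed before the data were examined were 32 gene lists: 22 of pathways and 10 of cell types. The 26 with at least 5 measured genes were tested with camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 26. All 9 calls were lost with an estimated correlation (adjusted p = 0.825 for each) and none was made by fry, which tests a list by itself (1 list, immediate early genes, had an unadjusted p under 0.05, 0.0301). Counts within a list are given over all genes tested and adjusted over the list alone. Named genes were the up to 10 with the largest rise and fall among those past the threshold with a mean of at least 20 and no overlap between groups, the 5 with the smallest p each way, up to 4 members per list that passed, filled to 2 with the most abundant members, and Mertk and Rpe65. Not every gene that the rule allowed is reported here. Named outside this rule, after their values were seen, were list members that passed adjusted over the list alone or in the authors' deposited table, Ryr1, Tslp, Aldh1a3, Smad3, Nrip1, Hic1, Oasl2, Trib3, Acot2, Cdsn, Gapdh and the genes of the closing hypotheses.

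Replicates were compared before use. The chi-square per degree of freedom over genes between libraries of one group was 8.58 to 61.8, above sampling noise in every pair. The 10 most abundant genes took 10.7% to 11% of reads in 5 libraries and 8.23% in POS-challenged replicate 3. In a principal component analysis the first component held 51.3% of the variance and placed unchallenged replicates 1 and 3 at -36.8 and -26.2 and the other 4 libraries between 6.88 and 26.3. The second held 25.9% and placed POS-challenged replicate 3 at 35.9 and the others between -14.9 and -2.45. The labels give no sequencing batch.

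Alternatives laid down before the data were examined were quantile normalization, other minimum means, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, a fold threshold, the authors' deposited table, an estimated correlation and fry. Added afterwards were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and a fit without unchallenged replicates 1 and 3. The edgeR quasi-likelihood test called 8 genes higher and 3 lower, 11 of the 12 limma calls, and the DESeq2 run called 105 and 224, including all 308 of the authors' calls. Simulated counts for the 12556 genes, with 200 genes changed in 3 libraries against 3, were used to test the scripts: limma recovered 84% of the genes changed 2-fold and 100% of those changed 4-fold, with 12 false among 196 calls, and DESeq2 93% and 100%, with 38 false among 231. Of simulated lists, camera called 10 of 10 shifted by 0.5 on the log2 scale and 0 of 50 unshifted ones. Simulated genes varied independently of each other, so this does not show how often camera makes false calls on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.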

Results

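Primary cultures of mouse retinal pigment epithelium (RPE), the pigmented cell layer that engulfs the shed tips of photoreceptors, were profiled by RNA sequencing with and without a meal of photoreceptor outer segments (POS). Cells came from C57BL/6J mice aged 10 to 12 days and had grown for 5 to 6 days on permeable supports with 0.4 µm pores. Challenged cultures received about 10 POS per RPE cell for 1.5 h and were then washed, and unchallenged cultures received none. The unchallenged libraries are titled Veh in the labels, which may stand for vehicle. Each group had 3 libraries, described in the labels as biological replicates, and 12556 genes were measured. The reads summed over these genes came to 28808338, 26606536 and 25667464 in unchallenged replicates 1, 2 and 3, and to 30406411, 30420028 and 24869273 in POS-challenged replicates 1, 2 and 3. Gene levels are given as normalized read counts, mean ± SD. Log2 fold changes are on the log2(value + 1) scale, challenged over unchallenged, and understate the change of low genes.

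The comparison of challenged with unchallenged cells asked which transcripts in the cultures differed soon after contact with outer segments. Sag, the gene of rod arrestin, showed the largest rise among genes past the threshold, from 21.9 ± 4.40 to 830 ± 220 normalized counts (n = 3 per group), a log2 fold change of 5.16 ± 0.24 (SE; limma adjusted p = 0.00109). Cdhr1, a cadherin found at the base of photoreceptor outer segments, rose from 104 ± 27.8 to 459 ± 103 (log2 fold change 2.13, adjusted p = 0.0417). For both genes, RNA carried in with the outer segments cannot be told apart from induction in the RPE. The retinoic acid receptor gene Rarb rose from 418 ± 53.2 to 1292 ± 184 and Cyp26b1, whose product degrades retinoic acid, from 231 ± 16.6 to 669 ± 123 (log2 fold changes 1.62 and 1.52, adjusted p = 0.0203 and 0.0278). Hmcn2, which codes for an extracellular matrix protein of the hemicentin family, showed the largest fall among genes past the threshold, from 318 ± 17.9 to 145 ± 6.03 (log2 fold change -1.13, adjusted p = 0.0278).

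In all, 8 genes rose and 4 fell at an adjusted p under 0.05, and in each of the 12 the 3 challenged values lay on one side of the 3 unchallenged ones. Mbd1, a reader of methylated CpG sites, rose from 1733 ± 119 to 3829 ± 144 (log2 fold change 1.15, adjusted p = 0.0047). Cep85l, a centrosomal gene, rose by 1.07 on the log2 scale, from 211 to 446. Synpo, which codes for the actin-associated protein synaptopodin, rose by 0.79 from 6587 to 11376, and the mitochondrial NAD carrier gene Slc25a51 rose by 0.57 from 2793 to 4154 (adjusted p = 0.0417 for each of these 3). Among the genes that fell, Fam46a dropped by 0.80 on the log2 scale, from 2998 ± 191 to 1724 ± 172. Pnrc1, a nuclear receptor coactivator, dropped by 0.63 from 2168 ± 43.3 to 1400 ± 53.3, and Ccng2, the gene of cyclin G2, dropped by 0.63 from 1830 ± 67.9 to 1185 ± 66.2 (adjusted p = 0.0421, 0.0336 and 0.0421).

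On the mouse assembly GRCm38.p6, Sag (Entrez Gene 20215) lies on chromosome 1 from 87798143 to 87845158. Cdhr1 (170677) and Rarb (218772) lie on chromosome 14, from 37077849 to 37098347 and from 16430839 to 17082331. Mbd1 (17190) and Synpo (104027) lie on chromosome 18, from 74267605 to 74282737 and from 60593981 to 60660173, and Cyp26b1 (232174) on chromosome 6 from 84571414 to 84593908. Slc25a51 (230125) and Pnrc1 (108767) lie on chromosome 4, from 45395923 to 45408917 and from 33245423 to 33248787. Cep85l (100038725) spans 53273441 to 53379883 on chromosome 10, Hmcn2 (665700) 31314255 to 31460738 on chromosome 2, Fam46a (212943) 85320439 to 85327150 on chromosome 9 and Ccng2 (12452) 93267573 to 93276231 on chromosome 5. The table gives 1 value per gene, and whether reads were counted over exons or whole spans is not given in the sources used here. The protein-coding gene Pln overlaps the span of Cep85l and was not analysed here, so the value of Cep85l is uncertain to that extent.

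**Figure D1:**
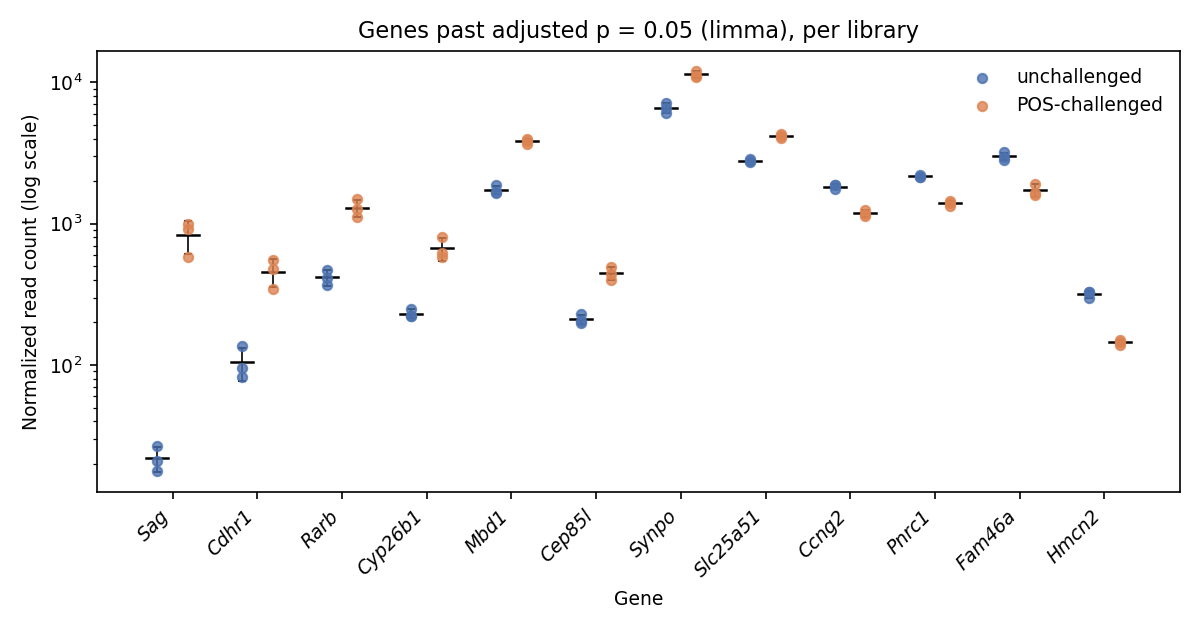
Normalized read counts (log axis) of the 12 genes that passed an adjusted p of 0.05 in limma, one point per library, with black bars at the mean and error bars of 1 SD (n = 3 per group). The challenged points of Sag lie between 578 and 987 and its unchallenged points between 17.9 and 26.6.

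Sag passed the threshold in all 6 fits that left out 1 library (adjusted p from 0.00144 to 0.0177), Mbd1 in 4 of 6 and each of the other 10 genes in 1 or 2. The number of genes past the threshold moved with the libraries kept: 2 higher and 0 lower without unchallenged replicate 1 or without POS-challenged replicate 1, 1 and 0 without unchallenged replicate 3 or without POS-challenged replicate 2, 12 and 108 without unchallenged replicate 2, and 10 and 3 without POS-challenged replicate 3, which kept 8 of the 12.

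The authors' deposited table, made with DESeq2, listed 105 genes higher and 203 lower at an adjusted p under 0.05, and these included all 12 genes above. All 308 had the same sign in limma and an unadjusted limma p under 0.05. Both tests used the same 6 libraries, so this is not independent support for those calls. Among genes of that table, chosen after their values were seen, the ryanodine receptor gene Ryr1 stood at 151 ± 40.4 unchallenged and 23.8 ± 12.0 challenged, and the cytokine gene Tslp at 163 ± 39.6 and 46.5 ± 19.4 (adjusted p = 6.88e-09 and 6.18e-05 in the authors' deposited table). Aldh1a3, which makes retinoic acid from retinal, stood at 124 ± 75.7 and 25.1 ± 1.84 (adjusted p = 8.19e-05 there). The signal transducer gene Smad3 stood at 5288 ± 587 and 8467 ± 294, the nuclear receptor cofactor gene Nrip1 at 580 ± 24.6 and 1033 ± 136, and the repressor gene Hic1 at 222 ± 18.3 and 414 ± 37.1 (adjusted p = 1.98e-07, 1.43e-07 and 2.46e-07 in the authors' deposited table). None of these 6 genes passed in limma, where adjusted p lay between 0.0774 and 0.226.

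Genes of inflammation had lower values in challenged cells, most of all against unchallenged replicates 1 and 3. All 28 measured NF-kB targets, cytokines and chemokines had a negative fold change, with a median of -1.30 (camera adjusted p = 1.71e-16, and adjusted p = 0.825 with an estimated correlation). In limma 0 of the 28 passed over all genes tested, 17 were lower adjusted over the list alone and 20 had an unadjusted p under 0.05, and 9 were lower in the authors' deposited table. Ccl20, a chemokine gene, stood at 648 ± 316 unchallenged and 156 ± 32.1 challenged, and the adhesion gene Icam1 at 1265 ± 390 and 529 ± 163. Nfkbia, the NF-kB inhibitor that NF-kB itself induces, stood at 4793 ± 1023 and 2722 ± 165, and Ptgs2, the inducible cyclooxygenase gene, at 9928 ± 1957 and 5945 ± 725 (limma adjusted p = 0.0208, 0.0236, 0.0208 and 0.0208 for the 4, over the list alone). Of the members with the highest levels, Lif stood at 33598 ± 4021 and 24965 ± 7462 and Csf1 at 11405 ± 3576 and 7403 ± 888 (adjusted p = 0.474 and 0.408). The size of the list's difference depended on unchallenged replicates 1 and 3, where interferon genes also stood high. Without both, which left 1 unchallenged library, the median was -0.29, and without unchallenged replicate 1 alone it was -0.75. The list mean, in log2 units, was 9.19 in unchallenged replicate 2 and 8.86 to 9.02 in the challenged libraries. The list's p does not single out the challenge: 2 other splits of the 6 libraries, which set unchallenged replicates 1 and 3 with POS-challenged replicate 1 or 2 against the rest, gave smaller adjusted p (1.03e-17 and 6.11e-20, medians -1.06 and -1.15). Further splits also passed in camera, with adjusted p of 8.11e-10, 0.00297 and 0.00812, and the remaining ones did not (0.0732 to 0.843).

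Immediate early genes, which cells induce within minutes of a stimulus, were lower as a group, with a negative fold change in 23 of 29 and a median of -0.27 (camera adjusted p = 3.06e-06, and adjusted p = 0.825 with an estimated correlation). Camera called at least 9 lists in 7 of the 10 splits of the libraries, so its p alone does not single out the challenge. Over all genes tested, 0 of the 29 passed in limma, and 16 had an unadjusted p under 0.05. Adjusted over the list alone, 6 were lower and 1 higher, and 5 were lower in the authors' deposited table. Junb stood at 4479 ± 274 unchallenged and 2750 ± 311 challenged, Maff at 7037 ± 405 and 4909 ± 785, Egr2 at 272 ± 50.2 and 173 ± 11.5, and Fosl2 at 17707 ± 1267 and 12967 ± 1669. Nr4a3, an orphan nuclear receptor gene, went the other way, from 136 ± 9.90 to 184 ± 9.72 (limma adjusted p = 0.0369 over the list alone). The members with the highest levels, Ctgf and Cyr61, stood at 107388 ± 6428 and 63251 ± 4507 unchallenged and at 89982 ± 16691 and 53183 ± 6674 challenged (adjusted p = 0.548 and 0.49).

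Interferon-stimulated genes showed the largest median of the 26 lists tested, -2.63, with a negative fold change in all 19 measured members (camera adjusted p = 3.06e-06, and adjusted p = 0.825 with an estimated correlation). The difference lay in part of the unchallenged libraries. The list mean, in log2 units, was 11.23 and 11.75 in unchallenged replicates 1 and 3, 6.59 in unchallenged replicate 2, and 6.05, 7.07 and 8.96 in POS-challenged replicates 1, 2 and 3. Ifit3, an antiviral gene, had 5553, 200 and 11726 normalized counts in unchallenged replicates 1, 2 and 3 and 139, 226 and 958 in the challenged ones. Bst2, the tetherin gene, stood at 5621 ± 4648 unchallenged and 842 ± 304 challenged (adjusted p = 0.404). In limma 0 of the 19 passed over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and 0 were called in the authors' deposited table. Without unchallenged replicates 1 and 3, which left 1 unchallenged library, the median turned to 0.66.

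**Figure D2:**
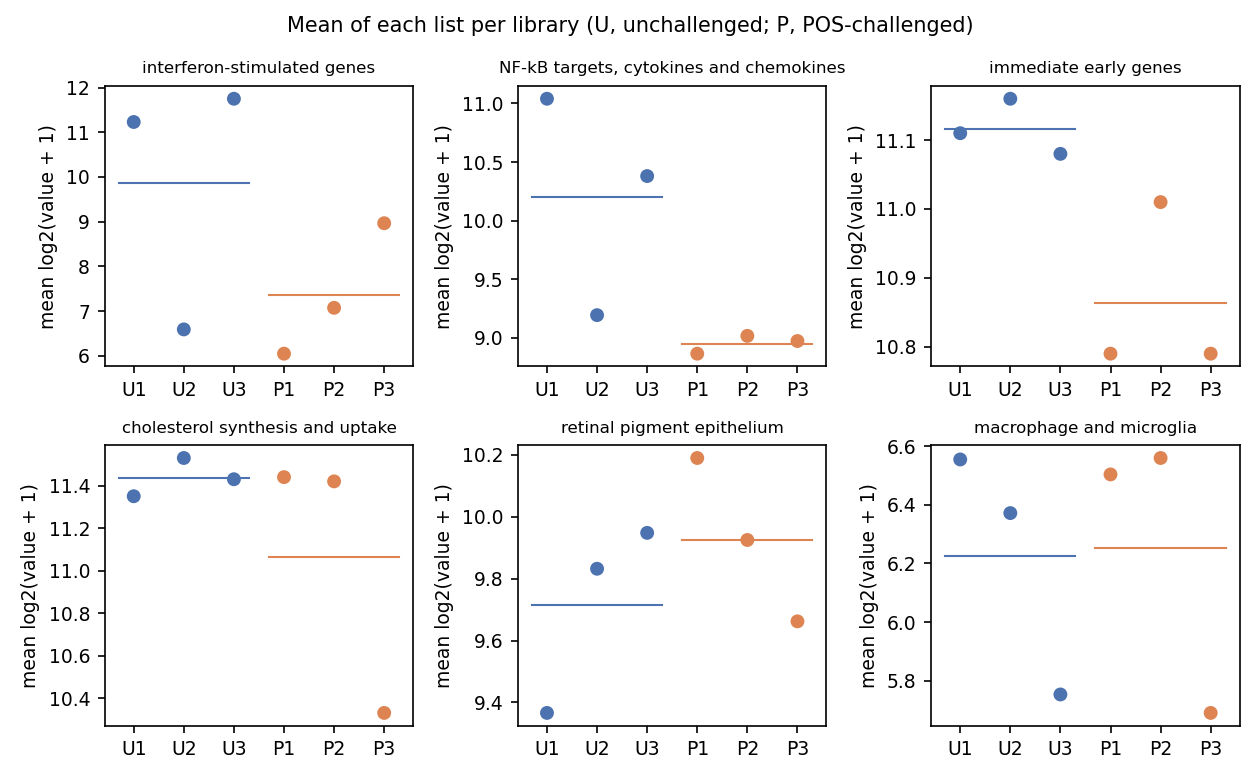
Mean log2(value + 1) of 6 gene lists in each library, U1 to U3 unchallenged and P1 to P3 POS-challenged, with a line at each group's mean (vertical scales differ between panels). The interferon mean is 11.23 and 11.75 in U1 and U3 and 6.59 in U2, and the cholesterol mean is 10.33 in P3 and between 11.35 and 11.53 in the other libraries.

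Genes of cholesterol synthesis and uptake were lower, with a negative fold change in 21 of 22 and a median of -0.36 (camera adjusted p = 0.00103, and adjusted p = 0.825 with an estimated correlation). That difference lay in POS-challenged replicate 3: Hmgcs1, an early enzyme gene of the pathway, had 16312, 17012 and 6508 normalized counts in POS-challenged replicates 1, 2 and 3 and 15259 to 19241 in unchallenged libraries, and without POS-challenged replicate 3 the median was 0.004 (adjusted p = 0.843). Genes of the lysosome and of phagosome maturation had a negative fold change in 26 of 33 and a median of -0.10 (adjusted p = 0.0042, and adjusted p = 0.825 with an estimated correlation), and -0.003 without POS-challenged replicate 3 (adjusted p = 0.378). Its most abundant members Ctsd and Gpnmb stood at 443107 ± 29884 and 161820 ± 16337 unchallenged and at 434912 ± 98971 and 156917 ± 28852 challenged. The lysosome call also ended with quantile normalization (adjusted p = 0.337). In limma 0 members of either passed over all genes or adjusted over the list alone, 0 and 7 had an unadjusted p under 0.05, and the authors' deposited table called 0. Scd2 and Fasn, the most abundant of 11 LXR-linked genes of sterol efflux and lipid synthesis, stood at 52586 ± 2394 and 21389 ± 628 unchallenged and at 40935 ± 12230 and 18249 ± 3561 challenged, and that list did not pass (median -0.14, adjusted p = 0.474).

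Of the other metabolic and stress lists, glycolysis and lactate transport was lower, with a negative fold change in 12 of 14 and a median of -0.12 (camera adjusted p = 0.0078, and adjusted p = 0.825 with an estimated correlation). Without POS-challenged replicate 3 its median was -0.06 (adjusted p = 0.147). Its leave-one-out medians ran from -0.19 to -0.06, and it passed in 5 of the 6 fits. The pyruvate kinase gene Pkm stood at 139612 ± 9851 and 120261 ± 7813 and Aldoa at 104205 ± 1184 and 99881 ± 6227. The unfolded protein and integrated stress response had a negative fold change in 15 of 18 and a median of -0.15 (adjusted p = 0.0222, and adjusted p = 0.825 with an estimated correlation), with Hspa5, the main chaperone gene of the endoplasmic reticulum, at 51928 ± 7760 and 42519 ± 5502. That call ended without unchallenged replicate 1 (median -0.14, adjusted p = 0.07) and without unchallenged replicate 3 (-0.12, 0.159), with medians near that of the full fit. Without both high-interferon libraries the median was -0.02. Cytoplasmic ribosomal protein genes had a median of -0.09 with 27 of 32 negative (adjusted p = 0.0222, and adjusted p = 0.825 with an estimated correlation). Without unchallenged replicates 1 and 3, which left 1 unchallenged library, that median was 0.009. The ribosomal call ended without unchallenged replicate 1 (median -0.02, adjusted p = 0.596), POS-challenged replicate 1 (-0.05, 0.352) or POS-challenged replicate 2 (-0.04, 0.309). It stayed in 3 of the 6 leave-one-out fits, with the largest median, -0.16, without POS-challenged replicate 3 (adjusted p = 1.45e-06). The unfolded protein and ribosomal calls ended on the statistics of the authors' deposited table (adjusted p = 0.0722 each) and with DESeq2 on recovered reads (0.076 each), and all 3 calls ended with quantile normalization (0.194 for glycolysis, 0.0548 for the unfolded protein response and 0.304 for ribosomal proteins). In limma 0 members passed over all genes or adjusted over the list alone, 2, 1 and 1 had an unadjusted p under 0.05, and 0 were called in the authors' deposited table. Ribosomal protein genes and glycolytic genes such as Gapdh have near-identical processed pseudogenes, so their values are uncertain.

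Lists that did not pass in camera included fatty acid oxidation and PPAR targets (median 0.07 over 20 genes, adjusted p = 0.277), NRF2 targets and antioxidant enzymes (-0.13 over 20, 0.143), heat shock chaperones (-0.12 over 14, 0.145), oxidative phosphorylation (-0.02 over 26, 0.777) and autophagy and LC3 conjugation (-0.03 over 22, 0.205). Plin2, which coats lipid droplets, stood at 9688 ± 397 and 10069 ± 324, Hmox1, a heme oxygenase gene, at 70512 ± 875 and 64151 ± 1011, and the autophagy gene Map1lc3b at 6538 ± 438 and 6386 ± 45.5. Dnajb1, a chaperone gene, was lower in the authors' deposited table (adjusted p = 0.0314). Fatty acid oxidation passed without POS-challenged replicate 3 (median 0.13, adjusted p = 0.00588) and NRF2 targets without POS-challenged replicate 1 (median -0.18, adjusted p = 0.0164). None of the 13 mitochondrially encoded transcripts listed was analysed here.

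The machinery of outer segment uptake showed no group difference past the threshold. Genes of binding and engulfment had a median of -0.08 over 21 members (camera adjusted p = 0.379), and in limma 0 passed over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and 0 were called in the authors' deposited table. Mertk, the receptor required for engulfment, stood at 3017 ± 524 and 3559 ± 907 (log2 fold change 0.22 ± 0.21 SE, adjusted p = 0.711), its ligand gene Gas6 at 29733 ± 6515 and 30886 ± 5608, and Anxa2 at 31133 ± 406 and 28238 ± 3534. Phosphoinositide enzymes and signalling genes had a median of 0.01 over 43 members (adjusted p = 0.719). Their most abundant members Akt1 and Inppl1 stood at 7542 ± 100 and 5883 ± 538 unchallenged and at 7603 ± 457 and 5422 ± 467 challenged. Pik3c2a, a class II phosphoinositide 3-kinase gene, stood at 6087 ± 320 and 4852 ± 192 and was lower in the authors' deposited table (adjusted p = 0.00885), with 0.24 in limma.

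Visual cycle genes as a list did not pass (median 0.04 over 12 members, camera adjusted p = 0.277), although Dhrs3, which reduces retinal to retinol, stood at 484 ± 79.8 unchallenged and 1234 ± 250 challenged. Dhrs3 was higher adjusted over the list alone (limma adjusted p = 0.00103) and in the authors' deposited table (adjusted p = 3.65e-10), with 0.0774 over all genes in limma. Rpe65, the retinoid isomerase gene that marks RPE, stood at 136 ± 32.4 and 157 ± 44.7 (log2 fold change 0.19 ± 0.25 SE, adjusted p = 0.788). Genes of melanin synthesis and melanosomes had a median of 0.01 over 13 members (adjusted p = 0.474). Among them Rab38, a melanosome transport gene, was higher adjusted over the list alone (limma adjusted p = 0.00439), at 525 ± 57.3 and 882 ± 94.3, and Tyr, the tyrosinase gene, stood at 21709 ± 4685 and 21990 ± 5455. Both lists passed without POS-challenged replicate 3 (medians 0.20 and 0.23, adjusted p = 0.0105 each), and the visual cycle list also without unchallenged replicate 3 (median 0.11, adjusted p = 0.0412).

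Circadian clock genes had a median of 0.10 over 16 members and did not pass as a list (camera adjusted p = 0.277), but 3 were higher and 1 lower adjusted over the list alone. Per2, a repressor of the clock, stood at 77.3 ± 21.7 and 177 ± 39.9, the transcription factor gene Hlf at 63.7 ± 15.0 and 120 ± 2.05, and Nr1d1 at 642 ± 36.2 and 906 ± 189 (limma adjusted p = 0.0159, 0.0159 and 0.0493 over the list alone). Bhlhe40 stood at 18874 ± 720 and 15377 ± 473 (limma adjusted p = 0.0223 over the list alone). In the authors' deposited table, 2 clock genes were higher and 1 lower. Genes of epithelial-mesenchymal transition had a median of -0.01 over 20 members (adjusted p = 0.516), with Fn1 at 179031 ± 29054 and 148078 ± 21519. Cell cycle genes had a median of 0.10 over 18 members (adjusted p = 0.155). They passed without unchallenged replicate 1 (median 0.27, adjusted p = 0.000282) and without POS-challenged replicate 3 (0.17, 0.0113). Without unchallenged replicates 1 and 3, which left 1 unchallenged library, their median was 0.28. Pcna stood at 1538 ± 77.1 and 1288 ± 22.1.

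**Figure D3:**
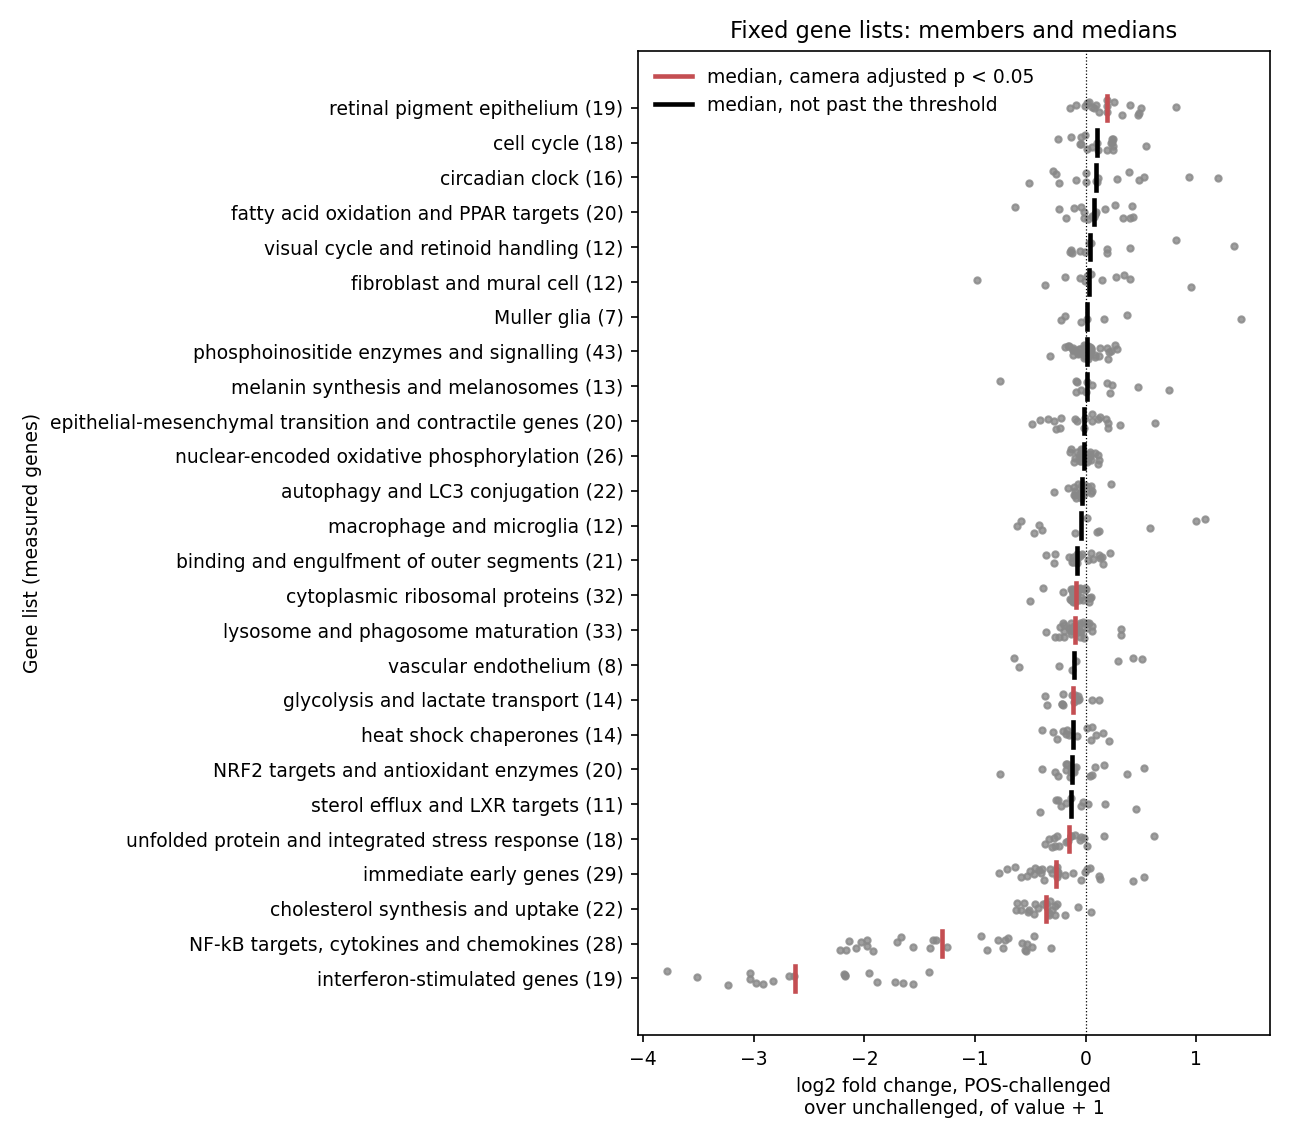
Log2 fold change, challenged over unchallenged, of each measured member (grey points) of the 26 gene lists tested, with a bar at the median, red where the camera adjusted p was under 0.05. The medians of the interferon and NF-kB lists, -2.63 and -1.30, lie apart from those of the other lists.

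Markers of cell types were compared next. RPE markers were higher as a group, with a positive fold change in 16 of 19 and a median of 0.19 (camera adjusted p = 0.0222, and adjusted p = 0.825 with an estimated correlation). In limma 0 of the 19 passed over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and 0 were called in the authors' deposited table. Krt18, a keratin gene, stood at 7863 ± 839 and 9371 ± 544. Many RPE markers, such as Rpe65 and Tyr, are also in the visual cycle or melanin lists, which did not pass. The RPE list mean, in log2 units, overlapped between groups. It was 9.366, 9.832 and 9.948 in unchallenged replicates 1, 2 and 3 and 10.19, 9.925 and 9.662 in the challenged ones. The median was -0.02 without POS-challenged replicate 1 (adjusted p = 0.591), 0.005 without unchallenged replicate 1 (adjusted p = 0.392) and 0.17 without POS-challenged replicate 2 (adjusted p = 0.114), and the call also ended with quantile normalization (adjusted p = 0.0548). Of 28 rod photoreceptor genes listed, 1 was measured, Sag, and of 10 cone genes 0 were, and the others were not analysed here for a reason that is not known. Müller glia (7 genes, adjusted p = 0.516), macrophage and microglia (12 genes, 0.726), vascular endothelium (8 genes, 0.719) and fibroblast and mural cell markers (12 genes, 0.307) did not pass. The macrophage list had a median of -0.04 and a mean of 0.02, with its camera direction downward, and Cd68, its most abundant member, stood at 786 ± 21.5 and 734 ± 44.8. Pdgfra and Pdgfrb, growth factor receptor genes of the fibroblast list, were higher adjusted over the list alone (limma adjusted p = 0.0244 each), at 861 ± 179 and 1689 ± 478 and at 1580 ± 43.0 and 2013 ± 149. The Müller and fibroblast lists passed without POS-challenged replicate 3 (medians 0.20 and 0.25, adjusted p = 0.0114 and 0.00588). Glul, a Müller glia gene that RPE also expresses, stood at 11789 ± 1483 and 13346 ± 2510, Col1a1 at 40819 ± 8138 and 35637 ± 4342, and the endothelial gene Egfl7 at 199 ± 21.3 and 184 ± 27.7. Too few genes were measured for a test of inner retinal neurons (3), lens and ciliary epithelium (2) and erythroid cells (0), with Slc6a9 at 1974 ± 196 and 2090 ± 110 and Crybb3 at 127 ± 31.0 and 101 ± 28.2.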

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

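The count fits and the fit without unchallenged replicates 1 and 3 were chosen after the data were seen, and the other alternatives before. No alternative changed the direction of any of the 12 called genes, and all 12 stayed past the threshold with quantile normalization, pseudocounts of 0.1 and 5 and a minimum mean of 50. Dropping the minimum mean of 10 changes nothing, since it removes no gene. Counts of genes higher and lower were 8 and 4 in limma, 105 and 224 with DESeq2 on recovered reads, 105 and 203 in the authors' deposited table, 6 and 1 at an absolute log2 fold change of at least 1, and from 1 to 12 and from 0 to 108 when each library was left out (903 to 1689 genes at an unadjusted p under 0.05). Without unchallenged replicates 1 and 3 together, limma called 0 and 0 (403 genes at an unadjusted p under 0.05), with 1 unchallenged library left that is assumed to vary like the challenged ones. These fits have fewer samples. For the differences between tools the cause was not tested. With the replicate block, limma called 1 higher and 0 lower (1182 genes at an unadjusted p under 0.05). Deviations of same-numbered libraries correlated at -0.351, 0.172 and 0.173. So few values cannot tell whether the numbers pair the samples. The block changed no list call.

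Of 26 lists, 9 passed with the preset correlation, 4 with quantile normalization (cholesterol, immediate early, interferon and NF-kB), 7 on the statistics of the authors' deposited table and 7 with DESeq2 on recovered reads (both without the ribosomal and unfolded protein lists), 7 to 12 when each library was left out, and 0 with an estimated correlation or with fry. The NF-kB, immediate early and interferon lists passed in all 6 leave-one-out fits, with medians from -1.67 to -0.75, -0.35 to -0.25 and -4.38 to -1.73. Signs turned for cholesterol (leave-one-out medians from -0.58 to 0.0042) and RPE markers (-0.024 to 0.32), and, without unchallenged replicates 1 and 3, for interferon (0.66) and ribosomal protein genes (0.0091). The first turned without POS-challenged replicate 3 and RPE markers without POS-challenged replicate 1, and the cause was not tested. What depth limits was not tested: the lowest values are of 1 to 3 reads in a library, and genes with fewer than 87 reads over the libraries were not analysed here.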

Other observations

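Tests on the outer segment genes as a fixed ratio, the retinoid genes, the interferon genes and the number of lists were chosen only after the result they bear on was seen. Some genes that hypoxia induces, a group with no fixed list of its own, had lower values in challenged cells. Ak4, an adenylate kinase gene, stood at 3170 ± 239 normalized counts unchallenged and 2015 ± 317 challenged (n = 3 per group), Car9, a carbonic anhydrase gene, at 1091 ± 125 and 763 ± 108, and the angiogenic factor gene Vegfa at 30645 ± 1379 and 22827 ± 2441. The oxygen-sensing hydroxylase gene Egln3 stood at 2953 ± 569 and 1969 ± 249, and Bnip3 at 10542 ± 629 and 8708 ± 299. These 5 were picked because they were lower in the authors' deposited table (adjusted p from 0.000779 to 0.0431), and in limma their adjusted p lay between 0.199 and 0.283. A hypothesis is that the hypoxia response may be lower after the challenge. A list of other hypoxia-responsive genes, written before their values were looked at, had 22 measured members, 19 of them negative, with a median log2 fold change of -0.26 (camera p = 1.34e-06, and p = 0.0774 with an estimated correlation). Adjusted over the list alone 0 passed in limma, 11 were lower at an unadjusted p under 0.05, and 0 were called in the authors' deposited table. The median was -0.18 without POS-challenged replicate 3 and -0.11 without unchallenged replicates 1 and 3. Camera p was 2.41e-05 in the first of those fits, and the second left 1 unchallenged library. One other split of the 6 libraries gave a smaller p, 4.57e-07, with a median of -0.15. Further splits gave camera p of 1.56e-05, 0.000133 and 0.00689, with medians of -0.12, -0.14 and -0.11, and the remaining ones 0.107 to 0.559. So the set test alone does not single out the challenge. Ero1l stood at 24456 and 15265 and Lox at 76716 and 57240. Slc2a1 is also in the fixed glycolysis list.

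Sag and Cdhr1, both photoreceptor genes, rose together in challenged cells, and the challenge adds photoreceptor material. RNA carried in with the outer segments is a candidate source. The excess of Sag over that of Cdhr1 was 2.41, 2.16 and 2.29 in POS-challenged replicates 1, 2 and 3. That is a single ratio within counting error and the spread of unchallenged libraries (chi-square p = 0.74). It is what 1 source would give, but a joint induction in the RPE could give it too, so the ratio does not decide between them. Only 1 of 28 rod genes was measured, and whether the others were too low or were left out for another reason is not known, so carried-in RNA and induction in the RPE cannot be told apart by the rod list. In a wider list of photoreceptor genes written afterwards, 4 of 48 were measured (median log2 fold change 0.34), of which Unc119 and Rgs9 were higher in the authors' deposited table (adjusted p = 0.00867 and 0.0378), at 894 and 1051 unchallenged and 1349 and 1501 challenged. Both were already well above Sag in cells without added material.

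Rarb, Cyp26b1 and Dhrs3, genes that retinoic acid induces, were higher in challenged cells. The excess of each over that of Sag differed between the 3 challenged libraries, with 0.00697 as the largest chi-square p of the 3. The test allowed only for counting error and the spread of unchallenged libraries. Challenged libraries varied beyond counting error, with a chi-square per degree of freedom of 8.58 to 61.8 between pairs. The ratios therefore cannot tell whether RNA from the source of Sag gave the excess, and a carried-in share is not excluded. A candidate explanation is retinoid signalling, since outer segments carry retinal. Other retinoic acid-responsive genes, 24 measured, had a median log2 fold change of 0.028 (camera p = 0.558, and p = 0.738 with an estimated correlation, and 0.0361 with a preset correlation without POS-challenged replicate 3), with 3 higher (Rara, Rarg and Gprc5c) and 1 lower (Bhlhe40) adjusted over the list alone, and 3 higher and 4 lower at an unadjusted p under 0.05, so members going both ways leave this explanation open.

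Interferon-stimulated genes stood high in unchallenged replicates 1 and 3. A difference in macrophage content is argued against: the macrophage list mean spanned 0.802 log2 units over the 3 unchallenged libraries, with replicate 3 lowest, against 5.16 for the interferon list. A lowering by the challenge would set every unchallenged library above the challenged ones. The list mean of 6.589 in unchallenged replicate 2 lies instead within the challenged range, 6.046 to 8.965. That is 1 library, so a lowering by the challenge is neither carried nor excluded. A difference between cultures before the challenge may equally be the source and was not tested. Oasl2 had 3626, 83.1 and 3708 normalized counts in unchallenged replicates 1, 2 and 3, and 44.4, 76.8 and 383 in the challenged ones.

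POS-challenged replicate 3 stood apart in single genes: Trib3, a member of the unfolded protein and integrated stress response list, had 2995 normalized counts there and 422 to 694 in the other 5 libraries, Acot2 780 against 102 to 170, and Cdsn 687 against 58.0 to 102.

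Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 12 genes, and the highest other gave 2. For lists, 7 of the 10 splits, the real one included, gave as many as 9, and the highest other gave 14. With 10 splits a share under 0.05 cannot be reached, for genes or for lists.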
